A study of Homo sapiens with 8 samples.

How the data were processed

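The series held 8 RNA-seq libraries of MDA-MB-231 cells, a human triple-negative breast cancer line. Cells received DMSO vehicle or EMD37 at 0.5 µM for 12 h or 24 h, with 2 libraries per group, marked A and B. Per the labels' protocols, RNA was extracted with a Direct-zol kit and 1 µg of total RNA entered the TruSeq V2 RNA-Seq kit, which does not mark the strand. Per the submitters' processing notes, FastQC, STAR and DESeq2 were used on build hg38; their versions and roles, the program that counted reads and the strand setting were not given in the sources used here. The labels did not say whether replicates were separate cultures, so the p-values measure the spread between these libraries.

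The authors deposited read counts per gene as whole numbers (count), and these were the input to every test. The deposited normalized counts (signal) were the same reads divided by 1 size factor per library. For genes in both tables the ratio of the values was constant within each library to a relative range of 9.7e-10. The copy of the count table used here was cut off inside a line, part-way through the Ensembl IDs, and held 36715 genes, 30765 of them with reads. The normalized table held 27682 IDs, 6912 of them absent from that copy. Multiplying those values by the size factor gave whole numbers for all 55296 of 55296 values within 0.01, so their reads were recovered. The recovered genes entered an alternative and the closing observations, not the fit whose values are printed elsewhere, which used the count table alone.

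Reads in the count table ranged from 8.99 M to 11.44 M per library (M, mega), and the recovered genes added 8.26% to 11.66% of all reads. The RNA of RN7SL1 alone took 4.85% to 7.57%. The 37 mitochondrial genes in the count table had 0 reads, and several genes usually abundant in cultured cells had few. Across the 8 libraries ACTB averaged 8.14 CPM, MYH9 8.64, LMNA 16.9, B2M 19.8, ALDOA 7.92, PPIB 6.71, CALR 12.9 and FTH1 40.2. Others had the many reads usual for such genes, with ACTG1 at 4694 CPM, GAPDH at 2470, TPI1 at 1091 and CANX at 1922. The reason was not given in the sources used here, and the fold of such a gene rests on the few reads counted.

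Genes were named with the GENCODE 29 annotation on GRCh38 (hg38). In edgeR 4.0.16 under R 4.3.3, filterByExpr with a minimum count of 10 kept 14850 genes, and TMM factors ranged from 0.948 to 1.03. A model with 1 mean per group gave a common dispersion of 0.00537, a coefficient of biological variation of 0.0733 and 4 residual degrees of freedom. Genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p below 0.05. The 4 comparisons were EMD37 against vehicle at 12 h, the same at 24 h, the difference between these effects (the treatment by time interaction), and vehicle at 24 h against 12 h. Standard errors of log2 fold changes came from the fit. CPM values are means with the standard deviation of 2 libraries. Counts below 3, or 0.262 to 0.334 CPM, were treated as the floor; floors cover counting error only.

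Gene lists were fixed before the data were examined, as were the comparisons, thresholds and alternatives, except recovered reads, GC offsets and the omission of libraries for the shared calls, which were added later. The 28 lists covered the ATF4 and PERK arm, the ATF6 arm and ER chaperones, the IRE1 and XBP1 arm, ER-associated degradation, aminoacyl-tRNA synthetases, apoptosis regulators, G1/S and DNA replication, and G2/M and mitosis. Others held CDK inhibitors and p53 targets, cholesterol synthesis, fatty acid synthesis, lysosome, autophagy, NRF2 targets, heat shock response, hypoxia and glycolysis, NF-kB and inflammatory cytokines, interferon response, and extracellular matrix and EMT. The rest held N-glycosylation in the ER, ribosomal proteins, ribosome biogenesis and MYC targets, oxidative phosphorylation, core histones, AP-1 and immediate early genes, and markers of luminal breast epithelium, leukocytes and fibroblasts. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The leukocyte list had 4 tested members, below the minimum of 5, and got no test. Camera with an estimated correlation and fry were alternatives. A gene's count "adjusted over the list alone" used Benjamini-Hochberg adjustment within the list.

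Genes named in the report were chosen by a rule fixed in advance. It took 14 sentinel genes in both treatment comparisons, the 10 largest rises and 10 largest falls of each, and up to 4 members of each list by smallest p. It took 5 each way for the other 2 comparisons. The largest changes needed an adjusted p below 0.05 and at least 5 CPM in one group. Outside the interaction, both libraries of one group also had to lie above both of the other. Other genes are named where a sentence says they were chosen after the values were seen. Not every gene taken by the rule is printed in each comparison. At 24 h the effects of the sentinels ATF4, TRIB3, ASNS and PPP1R15A are left out.

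Alternatives covered other scalings (RLE, upper quartile), other filters, DESeq2 1.42.0, limma-voom, limma-trend on the normalized values, only the 4 libraries of a comparison, a 2-fold threshold, the recovered genes, offsets for GC content, leaving out each library, and a block for the replicate letters. The letters did not pair: correlations of A minus B differences between groups ran from -0.162 to 0.161, so no block entered the fit. A self-test drew counts from each gene's mean over all 8 libraries and its fitted dispersion, changed 200 genes in 1 group by known folds, and ran the same code. No other gene differed between groups. At 24 h it called 145 genes, against 6044 in the data, so its cutoff was stricter and its recovery need not match the data. It recovered 68.7% of 2-fold changes at 12 h and 73.1% at 24 h. For the interaction it recovered 59.7% or 53.7%, depending on the group that was altered. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Alternative splicing and read-level quality were not analysed here.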

Results

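MDA-MB-231 triple-negative breast cancer cells were profiled by RNA-seq after EMD37 at 0.5 µM or DMSO vehicle for 12 h or 24 h, with 2 libraries per group. Libraries held 8.99 M to 11.44 M counted reads (M, mega), and 14850 genes were tested. Correlations between replicates ran from 0.988 to 0.992. Errors given below are standard errors of log2 fold changes or standard deviations of CPM over 2 libraries, and gene calls were made with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

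At 12 h EMD37 raised the genes that cells switch on when unfolded protein gathers in the endoplasmic reticulum (ER). HSPA5, the ER chaperone BiP (ENSG00000044574, chromosome 9, 125234853 to 125241330 on hg38), rose 10.7-fold (log2 3.42, standard error 0.10), from 394 ± 30.8 to 4211 ± 436 CPM (n = 2). HERPUD1, an ER membrane protein of the degradation pathway (ENSG00000051108, chromosome 16, 56932048 to 56944863), rose by log2 3.89 (standard error 0.10). DDIT3, which encodes the stress transcription factor CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737), rose by log2 3.29 (standard error 0.12) from 17.8 ± 1.90 to 175 ± 22.1 CPM. In all, 782 genes rose and 510 fell at 12 h, 225 and 26 of them by at least 2-fold. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 4.9e-13 for HSPA5, 3.36e-13 for HERPUD1 and 1.1e-11 for DDIT3.

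All the fixed lists of the unfolded protein response were higher at 12 h. In the ATF6 arm and ER chaperones 21 of 24 tested genes rose (21 adjusted over the list alone), with a median log2 change of 1.23, camera adjusted p = 1.8e-79 and 0.0019 with an estimated correlation. SDF2L1 rose by 2.53, ERO1B by 2.46, MANF by 1.78 and HYOU1 by 1.75. In the ATF4 and PERK arm 21 of 28 genes rose (23 adjusted over the list alone), with a median of 0.95, camera adjusted p = 1.7e-70 and 0.0013 with an estimated correlation. DDIT4 rose by 3.98, the glutathione-degrading enzyme CHAC1 by 2.97, ATF3 by 2.71, ASNS by 2.55, TRIB3 by 2.04, the eIF2α phosphatase subunit PPP1R15A by 1.3 and ATF4 itself by 0.72. In the IRE1 and XBP1 arm 16 of 25 genes rose (19 adjusted over the list alone), with a median of 0.38, camera adjusted p = 1.5e-27 and 0.036 with an estimated correlation. DNAJB9 rose by 3.32, the coat protein gene SEC24D by 1.57, DNAJC3 by 1.32 and XBP1 by 1.22. In ER-associated degradation 12 of 25 genes rose and 1 fell (13 and 2 adjusted over the list alone), camera adjusted p = 1e-18 and 0.022 with an estimated correlation, with HERPUD1 far ahead of SEL1L at 1.31.

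**Figure D1:**
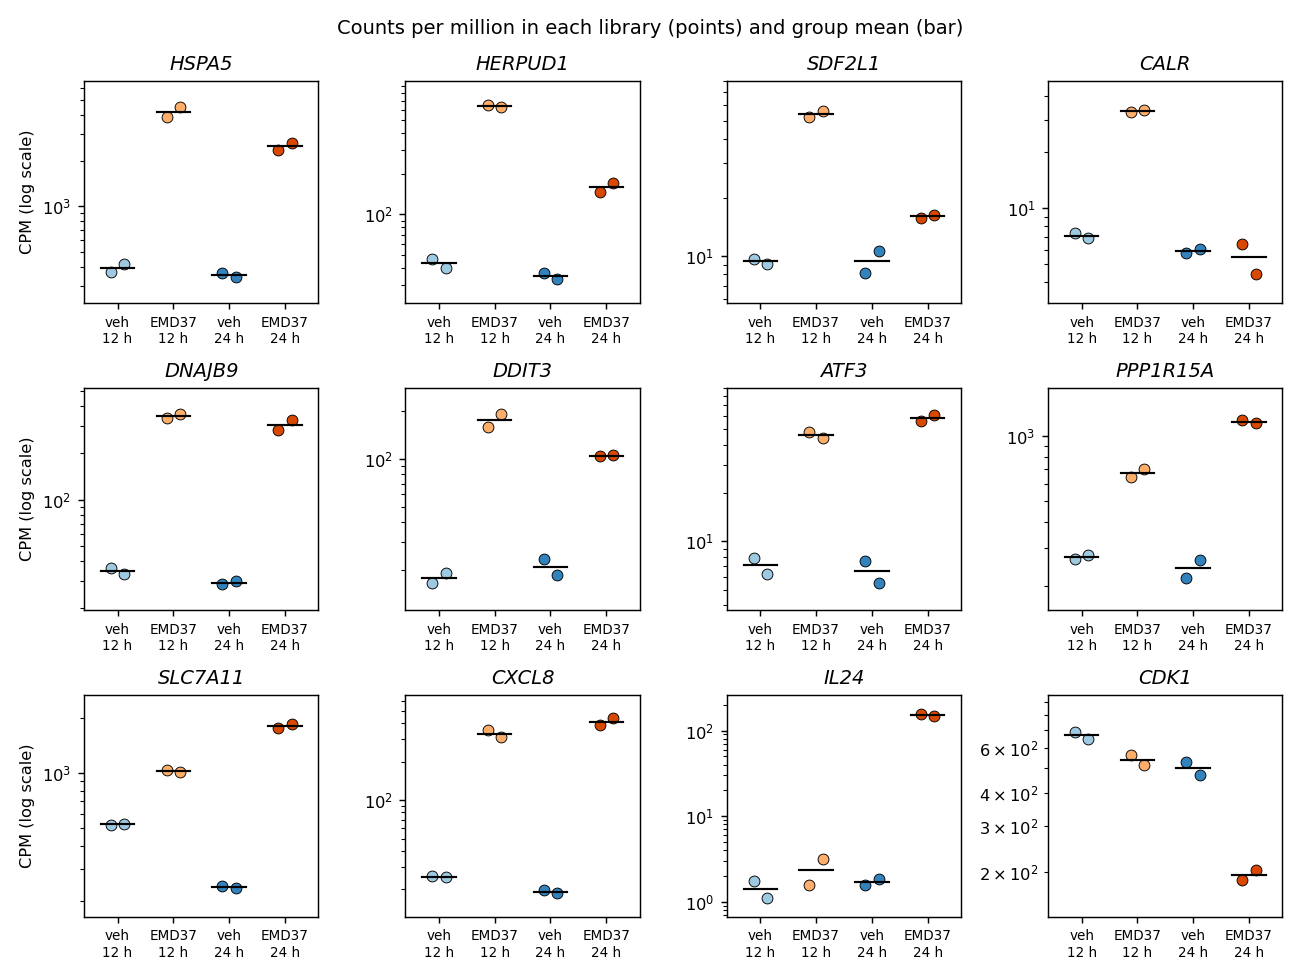
Points are CPM of single libraries and bars are group means (n = 2) on a log scale for 12 genes in vehicle and EMD37 cells at both times. HSPA5 went from 394 to 4211 CPM at 12 h and from 354 to 2484 CPM at 24 h. IL24 was called at 24 h alone, from 1.70 to 153 CPM, with an uncalled log2 change of 0.746 at 12 h.

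Stress programmes outside the ER also rose at 12 h. The heat shock response list had 11 of 22 genes higher (15 adjusted over the list alone), camera adjusted p = 7.2e-53 and 0.0083 with an estimated correlation. HSPA6 rose by 4.83 (standard error 0.14), the largest rise of the comparison, HSPA1A by 3.78, HSPA1B by 3.32 and DNAJB1 by 1.98; reads of the near-identical HSPA1A and HSPA1B may be shared between them and with HSPA6. NF-kB and inflammatory cytokines had 14 of 24 higher (22 adjusted over the list alone), with a median of 0.97, camera adjusted p = 1.4e-59 and 0.0026 with an estimated correlation. CXCL8 rose by 3.72, PTGS2 by 3.24, CXCL2 by 3.17 and IL6 by 2.94. NRF2 targets had 7 of 22 higher (9 adjusted over the list alone), camera adjusted p = 3.3e-07 and 0.019 with an estimated correlation, including HMOX1 at 2.49 and FTH1 at 1.82. FTH1 averaged 40.2 CPM across libraries, far below FTL at 3986 CPM, and 62.4% of its exonic bases lie in exons of another gene. Its fold is therefore uncertain. AP-1 and immediate early genes had 12 of 24 higher and 1 lower (14 and 1 adjusted over the list alone), camera adjusted p = 9.2e-14 and 0.039 with an estimated correlation, including KLF4 at 1.64 and DUSP1 at 1.59. Cholesterol synthesis had 9 of 23 higher (11 adjusted over the list alone), camera adjusted p = 3.5e-10 and 0.011 with an estimated correlation, led by INSIG1 at 2.10 and STARD4 at 1.77.

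Several lists at 12 h passed at the preset correlation and not with an estimated one. Autophagy had 8 of 25 genes higher and 1 lower, camera adjusted p = 8.6e-07 and 0.054 with an estimated correlation, with GABARAPL1 at 1.43 and SQSTM1 at 1.26. Aminoacyl-tRNA synthetases had 7 of 20 higher, camera adjusted p = 1.4e-06 and 0.15 with an estimated correlation, led by GARS1 at 1.56. Apoptosis regulators had 5 of 21 higher, camera adjusted p = 0.014 and 0.12 with an estimated correlation, including the inhibitor BIRC3 at 1.19. N-glycosylation in the ER had 5 of 27 higher, camera adjusted p = 0.023 and 0.21 with an estimated correlation; without replicate B of vehicle at 12 h it was 0.0711 and without replicate B of EMD37 at 12 h 0.0543. Markers of luminal breast epithelium passed upward with XBP1 as the only call among 13, camera adjusted p = 0.023 and 0.32 with an estimated correlation; it was 0.054 without replicate A of vehicle at 12 h and 0.0585 without replicate B of EMD37 at 12 h.

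Cell division genes moved little at 12 h. G1/S and DNA replication had 1 of 37 genes higher and 4 lower (1 and 10 adjusted over the list alone), with a median of -0.18, camera adjusted p = 0.0018 and 0.13 with an estimated correlation. PCNA fell by 0.47, with an edgeR adjusted p of 0.0639 without replicate B of EMD37 at 12 h, while the replication licensing gene CDC6 rose by 0.64. G2/M and mitosis had 3 of 38 lower (3 adjusted over the list alone), camera adjusted p = 0.0026 and 0.49 with an estimated correlation; CDK1 fell by 0.32 and CCNA2 by 0.32 (log2 -0.325). The CDK1 call ended without any 1 of the 4 libraries at 12 h, at edgeR adjusted p from 0.0765 to 0.337. The CCNA2 call ended without replicate A of vehicle (0.259) and without replicates A (0.12) or B (0.179) of EMD37. CDK inhibitors and p53 targets had 3 of 16 higher and 1 lower, camera adjusted p = 0.032 and 0.21 with an estimated correlation, with CDKN1A, which encodes p21, at 1.36. That list's value was 0.054, 0.0604 and 0.0543 without vehicle A, vehicle B and EMD37 B at 12 h, and 0.11 with offsets for GC content. Oxidative phosphorylation passed downward with 1 of 30 genes lower, camera adjusted p = 0.049 and 0.49 with an estimated correlation; it was 0.245 without vehicle A and 0.131 without EMD37 A at 12 h.

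Other lists did not pass at 12 h. The camera adjusted p was 0.97 for fatty acid synthesis, 0.46 for lysosome, 0.12 for hypoxia and glycolysis, 0.33 for interferon response, 0.81 for extracellular matrix and EMT and 0.82 for ribosomal proteins. It was 0.36 for ribosome biogenesis and MYC targets, 0.1 for core histones and 0.68 for fibroblast markers. The fatty acid list had a median of -0.02 and a mean of 0.01, while the test leaned down. Its sterol-linked regulator SREBF1 rose by 1.06 (edgeR adjusted p 0.0617 without vehicle A and 0.072 without EMD37 A at 12 h), and the triglyceride enzyme DGAT2 fell by 0.94. LIPA, which encodes lysosomal acid lipase, was not called at 12 h (-0.08, edgeR adjusted p = 0.649).

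Falls at 12 h were fewer and smaller than rises. The neuronal adhesion gene SLITRK5 fell by 1.43, EDN1, which encodes endothelin 1, by 1.41 (standard error 0.10), the long noncoding RNA gene LASTR by 1.27 and VCAN by 1.07. Other falls named by the rule were GOLGA2P5 (-1.29), FRMD4B (-1.24), PYROXD2 (-1.17), GVQW3 (-1.08), LCT-AS1 (-1.32) and APLN (-1.18), and LURAP1L joined the largest rises at 3.35. LCT-AS1 gave an edgeR adjusted p of 0.0503 without vehicle A and 0.0994 without EMD37 A at 12 h, and APLN 0.0973 and 0.204. The kit does not mark the strand, so the antisense LCT-AS1 is uncertain in name. How reads matching several genes were counted was not given, so the pseudogene GOLGA2P5 is uncertain too. VCAN ended at an edgeR adjusted p of 0.0534 without replicate A of EMD37 at 12 h. Calls at 12 h depended on the libraries: rises numbered 444, 448, 427 and 387 without vehicle A, vehicle B, EMD37 A and EMD37 B at 12 h, and 1265 or 1271 without vehicle A or B at 24 h. Falls numbered 124, 211, 127 and 106 without those 12 h libraries in the same order, and 949 or 958 without the vehicle libraries at 24 h. CALR was counted at 7.12 CPM in vehicle at 12 h, far below CANX at 1528 CPM, so its rise of 2.23 rests on few reads.

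At 24 h the ATF4 and PERK arm, ER chaperone, heat shock, cytokine, NRF2 and autophagy lists were higher with EMD37 and the G1/S list was lower, each with a camera adjusted p of at most 0.022 with an estimated correlation. IL24, a cytokine gene (ENSG00000162892, chromosome 1, 206897443 to 206904139), rose by log2 6.49 (standard error 0.20) from 1.70 ± 0.182 to 153 ± 7.05 CPM (n = 2). HSPA5 rose by 2.81 (standard error 0.10) and DDIT3 by 2.32 (standard error 0.12). CDK1, the mitotic kinase (ENSG00000170312, chromosome 10, 60778331 to 60794852), fell by 1.36 (standard error 0.08). In all, 2916 genes rose and 3128 fell, 920 and 658 of them by at least 2-fold. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 4.71e-13 for IL24, 2.73e-12 for HSPA5 and 2.96e-09 for CDK1.

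The ATF4 and PERK arm was the strongest of the ER stress lists at 24 h. In it 26 of 28 genes rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 1.82, camera adjusted p = 1.7e-46 and 0.0069 with an estimated correlation. GDF15 rose by 5.06, ATF3 by 3.15, CHAC1 by 2.99, the cystine transporter SLC7A11 by 2.91 and SLC3A2 by 2.54. ATF5 went against the list and fell by 0.60, with an edgeR adjusted p of 0.0504 without replicate B of EMD37 at 24 h. In the ATF6 arm and ER chaperones 17 of 24 rose (18 adjusted over the list alone), with a median of 0.81. The camera adjusted p was 1.1e-13, and 0.022 with an estimated correlation. HYOU1 rose by 1.75, HSP90B1 by 1.35 and PDIA4 by 1.26. The sentinel gene SDF2L1 had a log2 change of 0.785. In the IRE1 and XBP1 arm 22 of 25 rose and 1 fell (23 and 1 adjusted over the list alone), camera adjusted p = 2.6e-16 and 0.079 with an estimated correlation; DNAJB9 rose by 3.38, HSPA13 by 1.33 and XBP1 by 1.24, while WFS1 fell by 0.57 (edgeR adjusted p 0.19, 0.0896 and 0.178 without vehicle B, EMD37 A and EMD37 B at 24 h). In ER-associated degradation 17 of 25 rose and 3 fell (17 and 4 adjusted over the list alone), camera adjusted p = 1.2e-05 and 0.12 with an estimated correlation; HERPUD1 rose by 2.18 and SELENOK by 1.57, while ERLIN2 fell by 1.07 and ERLIN1 by 0.40.

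Lists outside the ER were also higher at 24 h. NF-kB and inflammatory cytokines had 19 of 24 genes higher (20 higher and 1 lower adjusted over the list alone), with a median of 2.16, camera adjusted p = 5.6e-41 and 0.013 with an estimated correlation. IL6 rose by 4.54, CXCL8 by 4.42, PTGS2 by 4.26 and TRAF1 by 3.11. Heat shock response had 17 of 22 higher (18 adjusted over the list alone), camera adjusted p = 2.4e-28 and 0.022 with an estimated correlation, with HSPA6 at 5.45. Autophagy had 19 of 25 higher and 2 lower (19 and 2 adjusted over the list alone), camera adjusted p = 3.1e-13 and 0.022 with an estimated correlation; GABARAPL1 rose by 3.56 and the cargo receptor SQSTM1 by 3.46, while ULK2 fell by 0.85. NRF2 targets had 14 of 22 higher and 1 lower (14 and 1 adjusted over the list alone), camera adjusted p = 1.3e-11 and 0.013 with an estimated correlation, with HMOX1 at 2.41 and TXNRD1 at 1.89. Lysosome genes had 16 of 25 higher and 3 lower (16 and 3 adjusted over the list alone), camera adjusted p = 0.00062 and 0.12 with an estimated correlation, with NEU1 at 1.37; LIPA was again not called (-0.09, edgeR adjusted p = 0.46). AP-1 and immediate early genes had 15 of 24 higher and 4 lower, camera adjusted p = 4.3e-08 and 0.079 with an estimated correlation. Hypoxia and glycolysis had 14 of 31 higher and 8 lower, camera adjusted p = 0.00095 and 0.072 with an estimated correlation; the glucose transporter SLC2A3 rose by 2.51 and LDHA fell by 0.29, with an edgeR adjusted p of 0.0808 without vehicle A and 0.0714 without EMD37 A at 24 h. Aminoacyl-tRNA synthetases had 11 of 20 higher and 4 lower, camera adjusted p = 7.4e-05 and 0.18 with an estimated correlation; WARS1 rose by 1.16 and FARSB fell by 0.76.

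**Figure D2:**
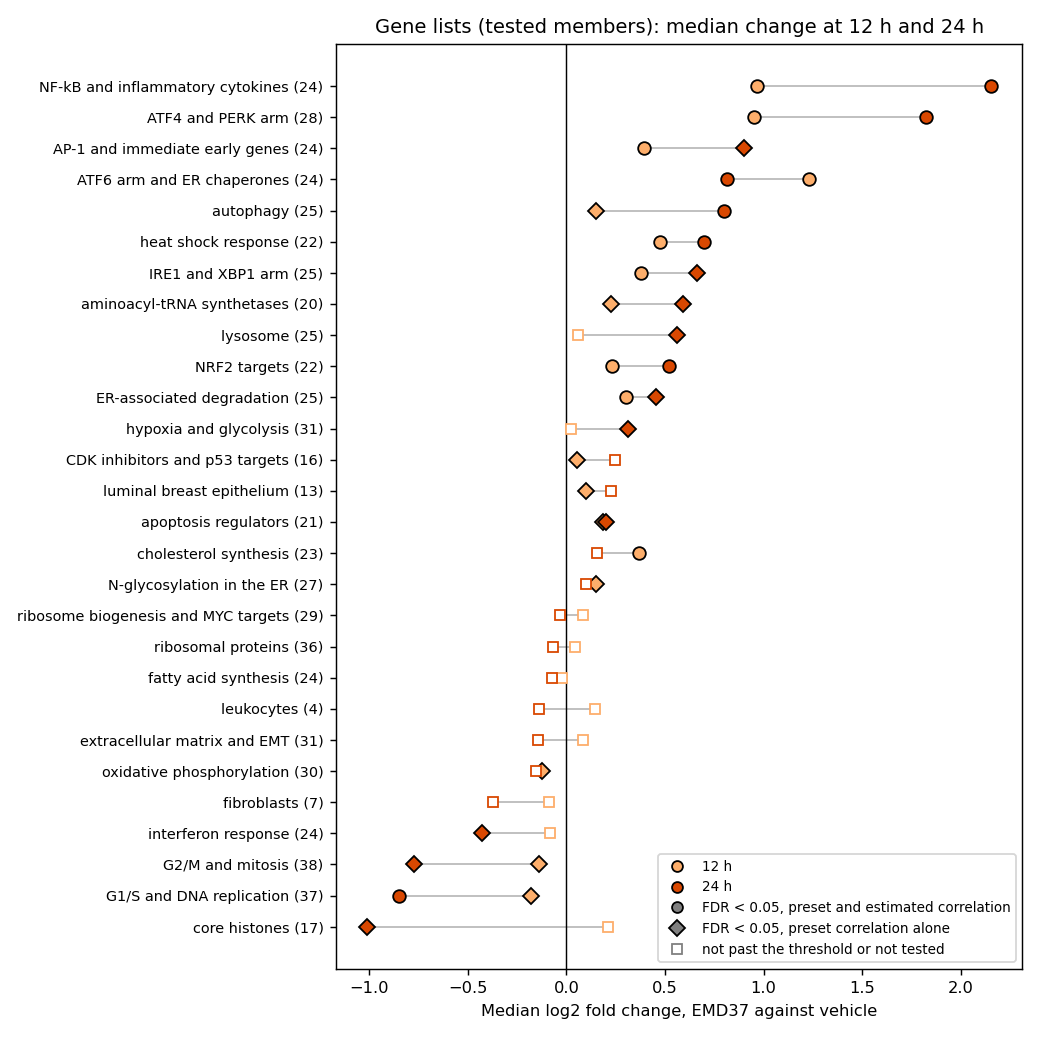
Each mark is the median log2 fold change of a fixed gene list at 12 h or 24 h (n = 2 libraries per group), with tested members in brackets and the fill showing which of the list tests were passed. NF-kB and inflammatory cytokines moved from 0.97 to 2.16, and core histones from 0.21 to -1.01.

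Division genes fell together at 24 h. G1/S and DNA replication had 35 of 37 genes lower (35 adjusted over the list alone), with a median of -0.85, camera adjusted p = 1.3e-19 and 0.013 with an estimated correlation; EXO1 fell by 1.56, RRM2 by 1.23, MCM10 by 1.18 and GINS1 by 1.09. G2/M and mitosis had 36 of 38 lower (37 adjusted over the list alone), with a median of -0.77, camera adjusted p = 2.7e-20 and 0.079 with an estimated correlation; TOP2A fell by 1.32, KIF20A by 1.28 and CCNA2 by 1.03. Core histones had 13 of 17 lower (13 adjusted over the list alone), with a median of -1.01, camera adjusted p = 3.1e-12 and 0.11 with an estimated correlation; H2AC20 fell by 1.63 and H2BC5 by 1.43. CDK inhibitors and p53 targets went both ways, with 5 of 16 higher and 7 lower, camera adjusted p = 0.32; CDKN1A rose by 0.73 (log2 0.725) and CDKN2C fell by 1.51. Apoptosis regulators also split, with 8 of 21 higher and 7 lower, camera adjusted p = 0.017 and 0.12 with an estimated correlation; the death-promoting PMAIP1 rose by 1.17 and BIRC3 by 2.45, while the death inhibitor BCL2L1 fell by 0.64.

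Interferon response genes were lower at 24 h, with 9 of 24 falling and 3 rising (9 and 3 adjusted over the list alone), camera adjusted p = 0.018 and 0.23 with an estimated correlation; it was 0.0615 without replicate A of vehicle at 24 h. IFIT1 fell by 1.18 and IFIT3 by 0.74, while MX1 rose by 0.97. The remaining lists did not pass, with camera adjusted p = 0.38 for cholesterol synthesis, 0.49 for fatty acid synthesis, 0.58 for extracellular matrix and EMT, 0.29 for N-glycosylation in the ER and 0.55 for ribosomal proteins. It was 0.8 for ribosome biogenesis and MYC targets, 0.2 for oxidative phosphorylation, 0.22 for luminal breast epithelium and 0.46 for fibroblast markers. The extracellular matrix list had a median of -0.14 and a mean of 0.08, since MMP3 rose by 4.21 and MMP1 by 2.76 while CCN2 fell by 1.62 and THBS1 by 1.25. Cholesterol synthesis had 8 of 23 genes higher and 7 lower, from INSIG1 at 1.25 to ACAT2 at -1.07.

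Among the largest falls that met the naming rule at 24 h, SMAD6 fell by 2.60 (standard error 0.20), ID3 fell by 2.56 (standard error 0.20) and ID1 fell by 2.33 (standard error 0.15). LASTR fell by 2.71, NEURL1B by 2.42 and the lipid droplet gene PNPLA3 by 2.22 (log2 -2.215), and DGAT2 fell by 1.85. CCDC190 fell by 2.90, LCT-AS1 by 2.78, KIAA1755 by 2.44 and APLN by 2.20. Among the largest rises were also LURAP1L at 5.33, TNFSF15 at 4.47 and HSPA1A at 4.21. Of the leukocyte markers 4 were tested and none was called at either time, with CD74 at 6.22 CPM and LAPTM5 at 83.7 CPM in vehicle at 12 h, and 2 of 7 tested fibroblast markers were lower at 24 h. With 2 libraries per group, the self-test recovered 44.8% of simulated 1.5-fold changes at 24 h, at a stricter cutoff than in the data. A gene that was not called is not shown to be unchanged.

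The log2 effect of EMD37 differed between the times for 2361 genes, with 1182 higher at 24 h and 1179 lower (the treatment by time interaction). Among called genes that met the naming rule, IL24 had the largest difference at 5.74, followed by PDE7B-AS1 at 3.57, GDF15 at 3.47, TCP11L2 at 3.44 and CAMK1G at 3.37. The antisense PDE7B-AS1 is uncertain in name, since the kit does not mark the strand. The largest negative differences under the same rule were CALR at -2.35, CCDC190 at -2.31, CRELD2 at -2.13, H3C12 at -2.06 and NEURL1B at -2.04. The ER stress markers parted: PPP1R15A was larger at 24 h by 0.97, HERPUD1 smaller by 1.71 and DDIT3 smaller by 0.98, while ATF3 (0.44, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.227), DNAJB9 (0.05) and XBP1 (0.03) were not called. HSPA5 was smaller by 0.61 (edgeR adjusted p = 0.00522), but 0.0542 without vehicle A and 0.0688 without EMD37 B at 12 h. ATF4 was larger by 0.37 (edgeR adjusted p = 0.025); without vehicle A, vehicle B, EMD37 A or EMD37 B at 12 h, or EMD37 B at 24 h, this was 0.0939, 0.0865, 0.14, 0.0586 and 0.0904. The higher calls numbered 735, 733, 677 and 701 without vehicle A, EMD37 A and EMD37 B at 12 h and EMD37 B at 24 h. The lower calls numbered 654, 694, 708, 513, 701 and 731 without vehicle A, vehicle B, EMD37 A and EMD37 B at 12 h and EMD37 A and B at 24 h.

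Lists with larger effects at 24 h included the ATF4 and PERK arm, with 13 of 28 genes larger and 3 smaller, camera adjusted p = 1.3e-08 and 0.053 with an estimated correlation. NF-kB and inflammatory cytokines had 12 larger and 1 smaller, camera adjusted p = 2e-08 and 0.076 with an estimated correlation, and autophagy 12 larger and 1 smaller, 1.3e-08 and 0.076. NRF2 targets gave camera adjusted p = 1.6e-06 and 0.053 with an estimated correlation, lysosome 0.00024 and 0.13, heat shock response 4e-04 and 0.25, hypoxia and glycolysis 0.0028 and 0.077, and the IRE1 and XBP1 arm 0.0073 and 0.54. In vehicle the median of heat shock response moved by -0.144 between 12 h and 24 h and that of the IRE1 and XBP1 arm by -0.143. Vehicle thus contributed to their differences (medians 0.28 and 0.232). The same held for the ATF4 and PERK arm, whose vehicle median moved by -0.189 against a difference of 0.46. For NF-kB and inflammatory cytokines the vehicle median moved by -0.061. Vehicle moved against the difference for lysosome (0.088), autophagy (0.085) and hypoxia and glycolysis (0.051), and by -0.004 for NRF2 targets. In EMD37 cells the heat shock gene HSPA6 changed by -0.39 and DNAJB1 by -0.56 (log2 -0.555) between 12 h and 24 h, so these 2 genes did not rise further. Of the IRE1 and XBP1 arm, DNAJC3 fell by 0.80 and HSPA13 rose by 0.62 in EMD37 cells, while XBP1, DNAJB9, SEC24D and WFS1 were not called. Lists with lower log2 effects at 24 h included G1/S and DNA replication (27 of 37 lower, camera adjusted p = 1.8e-20 and 0.037 with an estimated correlation). G2/M and mitosis had 28 of 38 lower, camera adjusted p = 2e-22 and 0.081 with an estimated correlation. In both lists the fall against vehicle deepened. Medians went from -0.18 at 12 h to -0.85 at 24 h for G1/S and from -0.14 to -0.77 for G2/M. In vehicle the G1/S median moved by 0.187 between the times, which added to its difference. The G2/M median moved by -0.197 in vehicle, which did not. Core histones had 12 of 17 lower, camera adjusted p = 2.5e-24 and 0.076 with an estimated correlation, and their median went from 0.21 to -1.01. In vehicle the core histone median moved by 0.323 between the times, so vehicle added to this difference too. Cholesterol synthesis had 8 of 23 lower and 1 higher, camera adjusted p = 0.0028 and 0.077 with an estimated correlation. Interferon response gave camera adjusted p = 0.025 and 0.3 with an estimated correlation, with 0.152 without vehicle A and 0.0672 without EMD37 A at 24 h. The other lists ran from a camera adjusted p of 0.11 for aminoacyl-tRNA synthetases to 0.91 for luminal breast epithelium. The ER-associated degradation list had a median of 0.11 and a mean of -0.05, and apoptosis regulators a median of -0.07 and a mean of 0.13.

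The ATF6 arm and ER chaperones had 8 of 24 genes smaller at 24 h and 3 larger (11 and 3 adjusted over the list alone), with a median of -0.27, camera adjusted p = 0.00069 and 0.12 with an estimated correlation. Split by vehicle CPM after the values were seen, the 12 members with more reads had a median of -0.01 and the 12 with fewer, which held 6 of the 8 smaller genes, -0.68 (log2 -0.675), and the Spearman correlation of level with interaction was 0.53. CALR (ENSG00000179218, chromosome 19, 12938578 to 12944489) was smaller by 2.35 and CRELD2 by 2.13. CALR was not called at 24 h (-0.12, edgeR adjusted p = 0.695), and its counts ran from 46 to 359 reads. Among members with more reads, MANF was smaller by 1.31 and HSPA5 by 0.61. The other calls among them were CANX, larger by 0.52, DNAJC10 by 0.43 and PDIA3 by 0.42, while HYOU1 was not called (0.01).

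**Figure D3:**
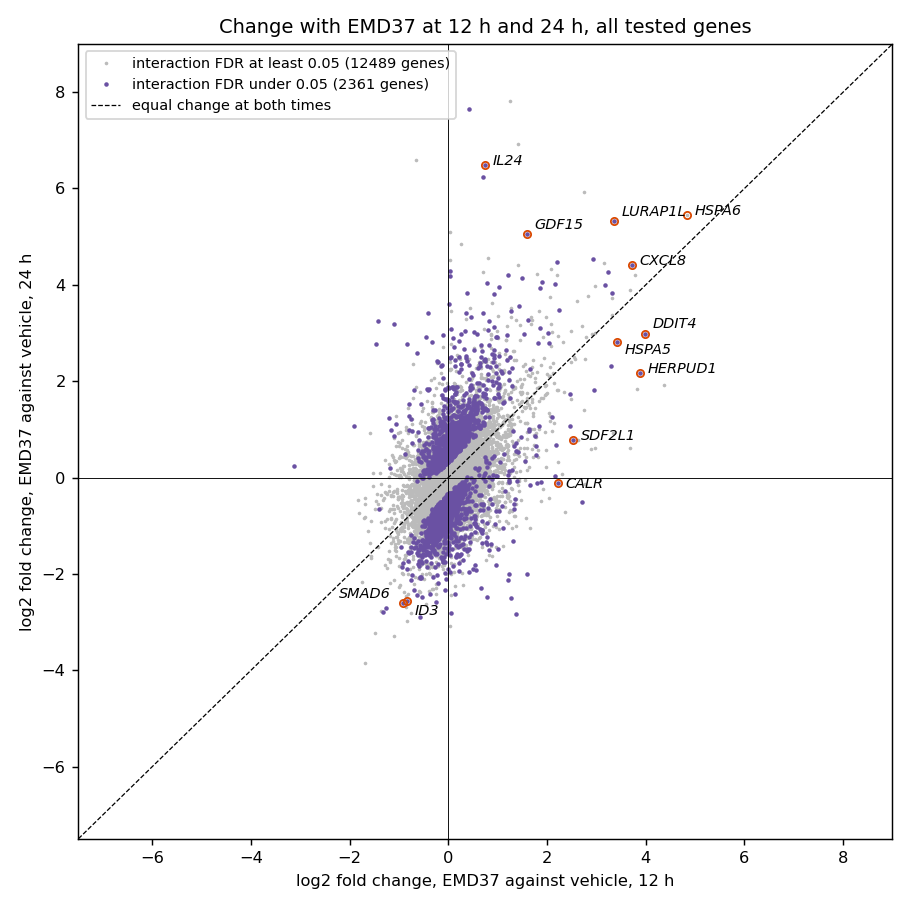
Each point is a tested gene with its log2 fold change at 12 h on the horizontal axis and at 24 h on the vertical axis; purple marks the 2361 genes with a treatment by time interaction and grey the others (n = 2 libraries per group). IL24 lies far above the diagonal, at 6.49 on the vertical axis.

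Effects at both times overlapped. Of the genes called at both, 621 rose at both (153.6 expected if calls were independent) and 365 fell at both (107.4 expected), while 18 rose and then fell and 19 fell and then rose. The correlation of the effects across genes was 0.499; genes are not independent of each other, so no p-value is attached. Shared calls numbered 499, 541, 476 and 432 without vehicle A, vehicle B, EMD37 A and EMD37 B at 12 h, and 1552 without vehicle B at 24 h.

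Vehicle cells also changed between the times, with 408 genes higher and 482 lower at 24 h against 12 h. IL11 rose by 1.81 (standard error 0.09), FBLN1 by 1.44 (log2 1.435), CSPG4 by 1.38, KLHL17 by 1.32 and PDE7B by 1.3, while the lactate transporter SLC16A1 fell by 2.75 (standard error 0.21) and the amino acid transporter SLC1A4 by 1.70 (standard error 0.16), UNC13A by 1.5, CCND2 by 1.49 and SCG5 by 1.49 (log2 -1.485). Some of these are unsteady. Without vehicle A at 12 h the edgeR adjusted p was 0.155 for FBLN1, 0.17 for CSPG4, 0.174 for KLHL17 and 0.071 for SCG5. CSPG4 also gave 0.0907, 0.0549 and 0.113 without vehicle B and EMD37 A at 12 h and vehicle B at 24 h. KLHL17 gave edgeR adjusted p 0.158, 0.0716, 0.0606, 0.392 and 0.0601 without vehicle B, EMD37 A and EMD37 B at 12 h, vehicle B at 24 h and EMD37 B at 24 h. The ATF4 and PERK arm was lower (9 of 28 lower and 1 higher, camera adjusted p = 1.5e-09 and 0.11 with an estimated correlation), as were aminoacyl-tRNA synthetases (0.0017 and 0.6), the IRE1 and XBP1 arm (0.0097 and 0.74), heat shock response (0.0097 and 0.6) and G2/M and mitosis (2.4e-08 and 0.6). G1/S and DNA replication (camera adjusted p = 1.2e-06 and 0.18 with an estimated correlation) and core histones (0.0022 and 0.72) were higher. The counts depended on single libraries: rises numbered 34, 72, 164, 176, 1564 and 249 without vehicle A, vehicle B, EMD37 A and EMD37 B at 12 h, vehicle A at 24 h and EMD37 B at 24 h. Falls numbered 55, 110, 226, 198 and 929 without the first 5 of these in the same order. In this comparison rises lay in GC-rich genes, with a correlation of log2 change with GC content of 0.382, so it may hold a library effect along with time in culture.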

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

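The results in this part were picked out because the effect of EMD37 differed between 12 h and 24 h in a direct test, or because they came from genes outside the count table. Among the tests below, the change within EMD37 cells, the small noncoding RNA test and the split of chaperones by level were chosen after the values were seen. The direct test put 1182 genes higher and 1179 lower at 24 h, so no single description covers both times. Of these genes, 356 were also called in vehicle over time, and there the controls changed as well.

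Lists differed between the times as well. Medians of the difference were 0.46 for the ATF4 and PERK arm, 0.23 for the IRE1 and XBP1 arm, 0.39 for lysosome, 0.43 for autophagy, 0.27 for NRF2 targets, 0.28 for heat shock response, 0.19 for hypoxia and glycolysis and 0.73 for NF-kB and inflammatory cytokines. They were -0.27 for the ATF6 arm and ER chaperones, -0.69 for G1/S and DNA replication, -0.64 for G2/M and mitosis, -0.43 for cholesterol synthesis, -0.29 for interferon response and -1.19 for core histones. With an estimated correlation, G1/S and DNA replication alone passed.

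Many named genes had higher log2 effects at 24 h, which for EDN1, a gene that fell at 12 h, meant a smaller fall. IL24 differed by 5.74, PDE7B-AS1 by 3.57, GDF15 by 3.47, TCP11L2 by 3.44, CAMK1G by 3.37, MMP3 by 3.01, TNFSF15 by 2.26, SQSTM1 by 2.20, GABARAPL1 by 2.13, MMP1 by 2.10 and LURAP1L by 1.98. IL6 differed by 1.60, BIRC3 by 1.26, TRAF1 by 1.26, DUSP10 by 1.25, NEU1 by 1.18, PDE7B by 1.05, PTGS2 by 1.02, MX1 by 1.00, CXCL2 by 0.82, EDN1 by 0.75, CXCL8 by 0.70 and IL11 by 0.39. Others were SLC7A11 at 1.94, SLC2A3 at 1.86, SLC3A2 at 1.61, TXNRD1 at 1.45, PPP1R15A at 0.97, FTH1 at 0.97, B2M at 0.95, PMAIP1 at 0.90, HSPA13 at 0.78, WARS1 at 0.58, CANX at 0.52, HSPA1B at 0.51, SELENOK at 0.44 and ATF4 at 0.37.

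Some differences came from vehicle more than from EMD37. SLC16A1 differed by 2.31, CCND2 by 2.40, UNC13A by 2.25, SCG5 by 1.11 and SLC1A4 by 0.84, while vehicle cells lost these transcripts between 12 h and 24 h, by 2.75 for SLC16A1. In EMD37 cells SLC16A1 changed by -0.45 (log2 -0.446). Vehicle moved more than EMD37 cells for SLC7A11 (-1.13 against 0.81), CXCL8, CXCL2 and IFIT1 as well. PTGS2, WARS1, HSPA1B and ATF4 among the genes above, and PCNA, IFIT3 and KIAA1755 among those below, were not called between the times in EMD37 cells. DDIT4 differed by -1.0 and WFS1 by -1.27, but vehicle cells rose by 1.25 and 0.91 (log2 0.908), while in EMD37 cells DDIT4 rose by 0.25 and WFS1 was not called (-0.37, log2 -0.366).

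Genes with lower log2 effects at 24 h, through a smaller rise, a turn to a fall or a deeper fall, included ER genes. CALR differed by -2.35, CRELD2 by -2.13, SDF2L1 by -1.74, HERPUD1 by -1.71, MANF by -1.31, DDIT3 by -0.98, ERO1B by -0.72, ERLIN2 by -0.68, DNAJC3 by -0.66, HSPA5 by -0.61, EDEM3 by -0.58 and SEL1L by -0.34. Division and histone genes were H3C12 at -2.06, H2AC20 at -1.84, H2BC5 at -1.65, EXO1 at -1.31, CDC6 at -1.3, RRM2 at -1.26, CDKN2C at -1.23, TOP2A at -1.05, CDK1 at -1.04, KIF20A at -0.99, GINS1 at -0.82, MCM10 at -0.73, CCNA2 at -0.71, CDKN1A at -0.64 and PCNA at -0.49.

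Other genes with lower effects were CCDC190 at -2.31, NEURL1B at -2.04, KIAA1755 at -1.81, ID3 at -1.71, SMAD6 at -1.67, ID1 at -1.63, LCT-AS1 at -1.46, LASTR at -1.45, STARD4 at -1.11, ACAT2 at -1.10, ACTG1 at -1.05, CCN2 at -1.04 and DUSP6 at -1.03. THBS1 differed by -0.96, DGAT2 by -0.92, ULK2 by -0.89, INSIG1 by -0.85, IFIT1 by -0.83, IFIT3 by -0.67, FARSB by -0.66 and BCL2L1 by -0.55.

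Genes whose reads were recovered from the normalized table also responded, with 87 higher and 39 lower at 12 h and 404 higher and 363 lower at 24 h. They are absent from the gene counts given in the report.

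The median effect of EMD37 was larger at 24 h for the ATF4 and PERK arm and smaller for the ER chaperones, with camera adjusted p = 0.053 and 0.12 with an estimated correlation. Within EMD37 cells the ATF4 arm moved by a median of 0.253 (0.209 to 0.269 with 1 library left out), with 12 of 28 genes higher and 7 lower. The chaperones moved by -0.31 (-0.402 to -0.246), with 5 of 24 higher and 12 lower. These medians argue against a change in vehicle alone, although the ATF4 arm moved by -0.189 in vehicle, with 9 genes lower and 1 higher. With GC offsets the ATF4 difference stayed at 0.545 (0.466 to 0.58). The chaperone difference was -0.291 with these offsets, against -0.272 without them, so removing the GC trend did not shrink it. With 1 library left out it ran from -0.381 to -0.189, and no value reached the -0.1 set for a GC effect. These values argue against GC content as the source of the chaperone difference. The -0.2 set beforehand against a GC effect was met by -0.291. It was missed without vehicle 12 h B, vehicle 24 h B or EMD37 24 h A (-0.189, -0.193 and -0.19). The chaperone difference was larger in members with fewer reads (median -0.675, against -0.008 for those with more), so the counting of genes such as CALR may account for part of it. Of the 12 members with more reads, HSPA5 and MANF were called smaller, while CANX (0.519), DNAJC10 (0.433) and PDIA3 (0.422) were called larger.

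Histone messages fell at 24 h by class. The 36 replication-dependent genes had a median of -1.389 and the 10 replacement genes -0.119, a difference of -1.27; genes of this kind are correlated (0.419 estimated), and the core histone list gave camera adjusted p = 0.11 with that estimate. The summed reads of the replication-dependent genes fell from 10908 to 4851 CPM (log2 -1.169, -1.558 to -0.764 over pairs of single libraries). Moving counted reads between near-identical copies cannot change this sum, but how reads matching several copies were counted was not given. A general loss of RNA without poly(A) tails would have lowered small noncoding RNAs too, if these entered the libraries as histone messages do. Their median was 0.15, with quartiles from -0.267 to 0.494. Whether both entered alike was not measured, so a lower yield of histone messages stays open. Fewer cells in DNA synthesis could give the fall of histone messages, alongside the fall of G1/S genes. Faster decay of histone messages stays open as well, since neither was measured.

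Vehicle cells changed with time along GC content. In the GC-richest of 3 equal groups of genes lay 265 of 408 rises (65%), and 150 of 567 (26.5%) with GC offsets, a correction that removes the trend by construction and so cannot decide it. Vehicle replicates of the same time also differed along GC content, with correlations of B minus A of 0.327 at 12 h and 0.452 at 24 h. EMD37 replicates did too, at 0.138 and -0.28. The effect of EMD37 correlated with GC content at 0.15 at 12 h, -0.014 at 24 h and -0.106 for the interaction. Thinning all libraries to equal depth left the vehicle value at 24 h at 0.447. Thinning keeps each gene's expected share of reads. The value therefore argues only against counting noise at lower depth as the source of that replicate difference. Whether time in culture or library preparation caused the trend over time stays open, and vehicle time enters the interaction.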

How the results depend on the processing

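Recovered reads, GC offsets and the omission of libraries for the shared calls were added after the tables were examined; the other alternatives were fixed before. The alternatives covered the genes named by the fixed rule in each comparison; other interaction values given in the closing part were not run through them. No covered gene that was called changed sign. Covered genes that were not called did, such as LAPTM5 at 12 h (-0.134 to 0.069). With GC offsets the median of CDK inhibitors and p53 targets at 12 h went from 0.052 to -0.025. At 12 h, 782 genes rose and 510 fell as reported. Rises numbered 1394 with only the 4 libraries compared and 1185 with GC offsets; falls numbered 317 with DESeq2, 1109 with the 4 libraries and 848 with GC offsets. With 1 library left out, rises ranged from 387 (EMD37 12 h B) to 1271 (vehicle 24 h B) and falls from 106 to 958 for the same libraries. At 24 h the counts moved less.

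The interaction had 1846 higher calls with GC offsets and 722 lower calls with DESeq2. Higher calls ranged from 677 to 1615 and lower from 513 to 1621 without EMD37 12 h B and vehicle 24 h A. Vehicle time was the least stable. It had 623 rises with no filter beyond 1 count, 267 with DESeq2, and 42 rises and 83 falls with only 4 libraries. Its rises ranged from 34 to 1564 and its falls from 55 to 929 without vehicle 12 h A and vehicle 24 h A.

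With an estimated correlation 9 lists passed at 12 h, 7 at 24 h and 1 for the interaction. Genes called at both times with the same sign numbered 154 with a fold of at least 2, and from 432 to 1552 without EMD37 12 h B and vehicle 24 h B.

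Of 93 covered genes called at 12 h, 67 stayed called in every setting; at 24 h 109 of 124 did, for the interaction 15 of 17, and for vehicle time 6 of 10. RLE and upper-quartile factors moved the median log2 change over all genes by at most 0.024. GC offsets moved some lists more: in vehicle over time the ATF4 and PERK arm went from -0.189 to -0.37 and AP-1 genes from 0.141 to -0.051, and the lysosome interaction from 0.392 to 0.497. With a block for the replicate letters, calls were 705 and 392 at 12 h, 2858 and 3037 at 24 h, and oxidative phosphorylation at 12 h reached a camera adjusted p of 0.05.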

Other observations

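The gene families and single genes in this part were chosen after the values were seen, so their p-values describe selected results. There were 12 families, most formed by gene name; the BMP and SMAD response genes were put together by function after SMAD6, ID1 and ID3 were seen to fall. MAP kinase phosphatases had 4 of 8 genes higher and 1 lower at 12 h, and 5 higher and 2 lower at 24 h, camera adjusted p with an estimated correlation 0.012 and 0.028. DUSP10 rose by 2.50 at 24 h while DUSP6 fell by 1.31. BMP and SMAD response genes had 5 of 7 lower at 24 h, camera adjusted p with an estimated correlation 0.063, with ID2 against them at 1.2 and SMAD7 not called (-0.13). Interleukin genes had 9 of 14 higher and 1 lower at 24 h, camera adjusted p with an estimated correlation 0.013.

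Genes found here only in the normalized table added long noncoding RNAs. In the fit with recovered reads, NEAT1, the paraspeckle RNA, rose by 1.56 at 12 h and 3.67 at 24 h, and MALAT1 by 0.42 and 1.61. TXNIP, a thioredoxin-binding protein induced by several stresses, was not called at 12 h (-0.14) and rose by 1.59 at 24 h. Between 12 h and 24 h vehicle MALAT1 went from 3104 to 1895 CPM and vehicle TXNIP from 308.5 to 172.5 CPM. Vehicle thus added to their larger effects at 24 h. In EMD37 cells MALAT1 went from 4138 to 5768 CPM and TXNIP from 280 to 519.2 CPM. NEAT1 went from 251.9 to 302 CPM in vehicle and from 743 to 3853 CPM in EMD37 cells. Of 3042 recovered genes tested, 87 rose and 39 fell at 12 h, and 404 rose and 363 fell at 24 h. Among the 18 genes that rose at 12 h and fell at 24 h was EDEM3, of ER-associated degradation.

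Some genes usually abundant in cultured cells had few reads. ACTB averaged 8.14 CPM beside ACTG1 at 4694 CPM, MYH9 averaged 8.64 CPM, and the 37 mitochondrial genes had 0 reads. Overlap with other annotated genes does not explain ACTB, MYH9 and LMNA, since 0% of their exonic bases lie in exons of another gene. The share was 53.5% for ALDOA, 62.4% for FTH1, 52.7% for CTSD and 27.2% for PPIB, so for these overlap stays open. The cause was not given in the sources used here.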
